A study of Bacillus subtilis with 14 samples.

How the data were processed

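Gene expression was measured in the Gram-positive soil bacterium Bacillus subtilis, strain background CU1065, on 14 two-colour arrays, on which cDNA from a pair of RNA samples is hybridised together. Per the labels' protocols, cultures were grown to an optical density of 0.4 and divided between 2 flasks. Vancomycin, a glycopeptide antibiotic that binds cell wall precursors, went into 1 flask at 2 µg/ml, and cells were harvested after 10 min. Per the same protocols, RNA was isolated with a column kit and treated with DNase, and 20 µg of total RNA was reverse-transcribed and labelled indirectly with a green dye (Alexa Fluor 555) or a red one (Alexa Fluor 647). Per the labels, untreated or wild-type RNA carried the 555 dye and treated or mutant RNA the 647 dye, except on 1 swapped array. The series text gives at least 2 independent RNA preparations per comparison but does not say which arrays share a preparation, so p-values measure the spread between arrays, part of which may be technical.

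The authors deposited 1 table of log2 ratios with 4116 rows, of which 10 are control probes (Brome mosaic virus and Escherichia coli) and 4106 are genes, with 1 row per gene. That the scale is log2 was read from the values, which pile up at the logarithms of small whole-number ratios. Scanner, background correction, normalization and spot averaging are not given in the sources used here. The deposited log2 values are not centred: array medians, once turned as described next, ran from -0.26 to 0.79, and centring moved the median gene by -0.11 for vancomycin in wild type, -0.33 for sigM with vancomycin and -0.56 for sigM untreated. No intensities were used here, so signal over background is unknown, and the number of arrays limits the precision. A value was taken as dim when it equalled the log2 of a ratio of whole numbers up to 12 after rounding to 4 decimals, those of the table. Such values made up 6.82% to 36.1% of each used array, and 986 genes had them on 6 or more of the 12 used arrays. Between 4064 and 4103 genes had a value on each used array, and 3878 had one on all of them.

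The 2 columns for vancomycin-treated against untreated sigM mutant were not used. The column of replicate 1 equalled wild-type vancomycin replicate 1 minus replicate 2, and the column of replicate 2 equalled wild-type replicate 2 minus that difference, within 0.0002 in 4110 of 4110 rows. The highest share of rows meeting such a relation among all other ordered triples of columns was 5.31%. Both columns were missing in all 6 rows where either wild-type vancomycin array had no value, and in 0 other rows. Dim values made up 2.1% and 3.54% of them, below every used array. The arithmetic alone does not say which columns were computed from which, and the missing rows and dim values are the basis for leaving out these. The response of the sigM mutant to vancomycin on its own arrays, and the interaction that needed it, were therefore not analysed here.

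The direction of the ratios is not stated with the values. The deposited strain arrays have the deleted genes positive, so they run wild type over mutant, the swapped array included, and all were turned to mutant over wild type. The vancomycin arrays likely run treated over untreated. The basis is the sigM gene itself: its wild-type over mutant ratio was 3.42 with vancomycin and 1.57 without, a difference of 1.85 ± 0.67 (SE), and its mean on the wild-type vancomycin arrays was 2.72 ± 0.58 (SE) as deposited. For yhdL, transcribed with sigM, the difference was 3.59 and the vancomycin value 2.44. The untreated sigM ratio was a whole or half-integer number within 6e-05 (log2) on 2 of 3 arrays, so it may be a lower limit set by a dim mutant channel. The sigM difference would then be an upper limit, which weakens this basis. If so, the channel order of the deposited ratios differs between both kinds of array.

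The log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient for each of 5 groups over the 12 used arrays, which left 7 residual degrees of freedom, a prior of 3.23 degrees of freedom and a prior variance of 0.591. The plan made before the data were examined had all 14 arrays and 6 groups in this fit. It called 0 genes for vancomycin in wild type against 18 here, 14 against 18 for sigM with vancomycin, 2 against 12 for sigM untreated, 64 against 190 for spx with vancomycin and 1 against 2 for spx untreated. For a gene raised alike on both wild-type arrays, the unused columns stand by their arithmetic near 0 and near the rise. That widens the residual spread of the gene, so the 0 in wild type follows in part from the columns themselves. Each group mean was tested against 0, two-sided, over the genes measured on every array of the group, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from the limma fit of the 12 used arrays. A pair of interaction contrasts, mutant over wild type with vancomycin minus the same without, was tested for sigM and for spx. No slide or scan batch was given. In every group but spx with vancomycin the dyes were not swapped, so those arrays alone do not tell a dye preference of a probe apart from the comparison, and other arrays of the same orientation were compared only for yhdN and yxnA.

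Before the data were examined, 26 gene lists were written from background knowledge: the sigM regulon and its core targets, the sigW, sigX, LiaRS and WalR regulons, Bce-type detoxification, peptidoglycan synthesis, teichoic acids, autolysins, Spx-activated and Spx-repressed genes, sulfate assimilation, general stress (sigB), heat shock and proteolysis, motility and chemotaxis, competence, early sporulation, ribosomal proteins, purine, pyrimidine, arginine and fatty acid synthesis, the F1F0 ATP synthase, and the PBSX and SPbeta prophages. List shifts were tested with limma's cameraPR at a preset correlation of 0.01 and again with camera at an estimated correlation, each adjusted over the 26 lists of a comparison. Both sigM lists were drawn in part by the study from these arrays and are not independent evidence of their direction. They also hold sigM, yhdL and yhdK, the mutated gene and the genes transcribed with it, whose falls in the sigM mutant say nothing about other members. Genes named in the text are the targeted genes (sigM, its anti-sigma genes yhdL and yhdK, and spx, listed as yjbD), up to 8 called genes of largest change per direction with the same sign on every array, filled to 4 where fewer passed, and up to 4 members per list with the smallest adjusted p. Other named genes were chosen after their values were seen. Names are those of the table, and 3036 of them matched a symbol of the reference gene table (assembly ASM904v1), while 1070 did not. That table was used only for names and gene order, and no coordinates are given because the files name no build.

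The fit was tested on simulated data for the same genes with genes changed by known folds. Their noise was normal and independent between genes, without dim values, so the rates may differ on the real arrays. For vancomycin in wild type, over 4100 genes, it recovered 3% of 67 genes changed 2-fold, 29.9% of 67 changed 4-fold and 95.5% of 66 changed 16-fold. For the sigM mutant with vancomycin, over 4053 genes, it recovered 51.6% of 64 genes changed 4-fold. For the spx mutant with vancomycin, over 4028 genes, it recovered 31.8% of 66 genes changed 4-fold. Unchanged genes made up 7 of 92, 5 of 97 and 1 of 76 calls in these comparisons, in the order given. Alternatives were median centring, scaling of the arrays to a common spread, separate fits, a replicate block, a dye term, array weights, robust eBayes, complete genes, 2-fold filters and leaving out each array. The dye term can be estimated only from the pair of spx arrays with vancomycin, which holds the swapped array. It shifts the other comparisons by part of the difference between those arrays, noise included, and is no test of the dyes there. The planned fit of all 14 columns was run as an alternative as well. Leaving out 2 columns, a fit with dim probes removed, the general stress list without yhdN, and a list of SOS (DNA damage response) genes were chosen after seeing the data.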

Results

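The series asked which Bacillus subtilis genes depend on sigma M under vancomycin stress. Sigma M is an extracytoplasmic function sigma factor, a subunit that directs RNA polymerase to cell envelope genes. Spx, a regulator of thiol homeostasis described as a sigma M target itself, was tested alongside. The used arrays compared wild type with and without vancomycin (2 arrays), the sigM mutant with wild type under vancomycin (3) and without it (3), and the spx mutant with wild type under vancomycin (2, of which 1 was dye-swapped) and without it (2). Values are log2 ratios with the SD over arrays. The p-values rest on the limma SE instead, and an SD of 2 arrays can be far smaller than it. Vancomycin ratios likely run treated over untreated, with the basis given under processing, and strain ratios are mutant over wild type. Replicate arrays correlated weakly across genes, which are not independent replicates: r was 0.334 for vancomycin in wild type, 0.291 for spx with vancomycin and 0.258 without. Replicate 3 of the sigM arrays stood apart, with r of -0.133 and -0.014 to the other arrays with vancomycin, and 0.055 and 0.064 without.

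The targeted genes were examined first. On the sigM mutant arrays, sigM stood at -3.42 ± 0.82 (SD, n = 3) with vancomycin and at -1.57 ± 0.68 (n = 3) without it, negative on every array, and the latter did not pass (limma, adjusted p = 0.154). The anti-sigma genes yhdL and yhdK, which follow sigM and are transcribed with it, fell by 6.68 ± 1.56 and 7.56 ± 0.79 with vancomycin and by 3.09 ± 0.58 and 3.53 ± 1.19 without. The yhdK ratio lay within 6e-05 (log2) of a whole or half-integer number on 3 of 3 arrays in each condition (ratios of 126.5 to 353 with vancomycin and 5.5 to 28 without), a match that chance gives for at most 5.9% and 0.47% of ratios of this size. Such ratios can arise where the mutant channel holds 1 or 2 units, so the yhdK falls may be limits set by that channel. The match held for sigM on 2 of 3 arrays without vancomycin (ratios of 2 to 5, chance at most 0.083%) and 0 of 3 with it, so its untreated value may be a limit too, and for yhdL on 1 of 3 arrays in each condition. The spx gene, listed as yjbD, fell by 5.67 ± 0.23 (n = 2) and 5.53 ± 1.55 (n = 2) in the spx mutant with and without vancomycin. In the spx mutant, sigM stood at 0.64 ± 1.42 and 0.62 ± 0.81, and neither value passed. In the sigM mutant, yjbD stood at -1.32 ± 0.41 (n = 3) with vancomycin and 0.51 ± 0.70 (n = 3) without, and neither passed (limma, adjusted p = 0.362 and 0.469), nor did their difference of -1.83 ± 0.61 (SE, limma, adjusted p = 0.611).

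Vancomycin in wild type raised 18 genes and lowered 0 of 4100 tested, while the planned limma fit of all 14 columns called 0. That 0 is no independent check, since the unused columns widen the spread of genes that respond. The strongest of the 18 were yvqI and yvqH (liaI and liaH, a small membrane protein and a phage shock protein A homologue of the envelope stress response), at 7.13 ± 1.39 and 7.06 ± 1.38 (SD, n = 2), or 140-fold and 133-fold. Next came yqjL, a putative hydrolase, at 5.05 ± 0.01, where the limma SE was 0.52. The lipid II flippase gene ydaH (amj) rose by 4.22 ± 0.23, and ywaC, encoding a (p)ppGpp synthetase, by 3.58 ± 0.58. The peptidoglycan precursor genes murG and murB rose by 3.01 ± 0.25 and 2.72 ± 0.42. All 18 genes changed the same way on both arrays, and the spx gene yjbD stood at 1.64 ± 0.15 without passing (limma, adjusted p = 0.358).

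The LiaRS regulon, a two-component system that answers cell wall antibiotics, had 5 of 6 measured members higher, and 6 adjusted over the list alone. Its median lay 3.73 above that of all genes, whose own median was 0.10. yvqG and yvqF stood at 4.27 ± 0.07 and 3.40 ± 0.21. The sigM regulon list had 11 of 56 members higher and 0 lower, 33 adjusted over the list alone, and a median 1.37 above all genes. Its members radC and maf, which lie beside the cell shape gene mreB, rose by 3.12 ± 0.26 and 2.80 ± 0.08, and 4 of 16 core targets rose. Both sigM lists were chosen in part on these arrays, so neither count is independent evidence. These 3 shifts held with an estimated correlation (adjusted p = 0.0183 for LiaRS, 0.000311 for the sigM regulon and 0.0136 for its core targets). The called genes outside every list were ywoB, at 3.62 ± 0.29, and yvtA (htrB, an envelope protease), at 2.59 ± 0.86, the latter named after its value was seen. The sigM gene itself, yhdL and yhdK stood at 2.72 ± 0.22, 2.44 ± 0.08 and 2.44 ± 0.85 and did not pass.

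The sigW regulon, a further envelope stress regulon, had a median 1.24 above all genes with 0 of 45 members called, 6 adjusted over the list alone, and all 45 means above 0. Its own median was 1.34, and 0.81 without replicate 2. yfhL stood at 2.80 ± 0.20 (limma, adjusted p = 0.0539) and ywrE at 2.12 ± 0.45. The list shift passed at the preset correlation (adjusted p = 1.32e-15) and not with an estimated one (adjusted p = 0.544 with an estimated correlation). Relative to all genes, the general stress list lay 0.66 higher, the Spx-activated list 0.59 higher and the mostly dim SPbeta list 0.49 higher. Motility and chemotaxis lay at -0.72, ribosomal proteins at -0.50, purine synthesis at -0.78 and the F1F0 ATP synthase at -0.94. None of these 7 lists had a called member, and all lost their call with an estimated correlation (adjusted p = 0.617, 0.574, 0.654, 0.544, 0.654, 0.574 and 0.403 with an estimated correlation, in the order given). Among their members, gsiB stood at 2.03 ± 1.16, trxB at 1.44 ± 0.89, fliF at -1.06 ± 0.33, rpsJ at -1.08 ± 0.00 and atpF at -0.93 ± 0.57. Each of these shifts but that of motility was lost or turned without 1 of the arrays. Without replicate 1 the list median was -0.23 for the ATP synthase, -0.30 for purine synthesis and 0.37 for general stress, and that of motility was -0.12 against -0.62. Without replicate 2 it was 0.39 for Spx-activated genes, -0.30 for ribosomal proteins and -0.05 for SPbeta, whose test then pointed down. With a dye term or a replicate block the ribosomal test pointed up (median 0.06 and 0.02). The dye term rests on the spx arrays with vancomycin alone, the only group with a swap. In peptidoglycan synthesis, 2 of 34 members rose (murG and murB) and the list did not shift (adjusted p = 0.12). The lists for sigX (adjusted p = 0.0928), Bce-type detoxification (0.131), the WalR regulon (0.227), teichoic acids (0.907), autolysins (0.227), Spx-repressed genes (0.699), sulfate assimilation (0.739), heat shock and proteolysis (0.086), competence (0.503), early sporulation (0.739), arginine (0.907), fatty acid (0.539) and pyrimidine synthesis (0.763) and PBSX (0.907) did not pass cameraPR.

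The lowest means of equal sign on both arrays belonged to ysbA and ysbB, at -4.62 ± 0.95 and -4.36 ± 1.25, followed by ydjM at -3.86 ± 4.30 and the dim yhjL at -3.17 ± 0.11. None of these passed. The glucosamine synthesis gene glmS stood at -2.85 ± 0.51 (limma, adjusted p = 0.202). At an unadjusted p under 0.05 there were 347 genes. Leaving out replicate 2 called 3 genes, 2 of them among the 18, leaving out replicate 1 called 27, 4 of them among the 18, a separate limma fit of these 2 arrays called 0, and centring each array called 16, all of them among the 18. A replicate block or a dye term called 4 each and array weights 44, while 192 genes were higher and 91 lower by at least 2-fold on both arrays without a test.

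**Figure D1:**
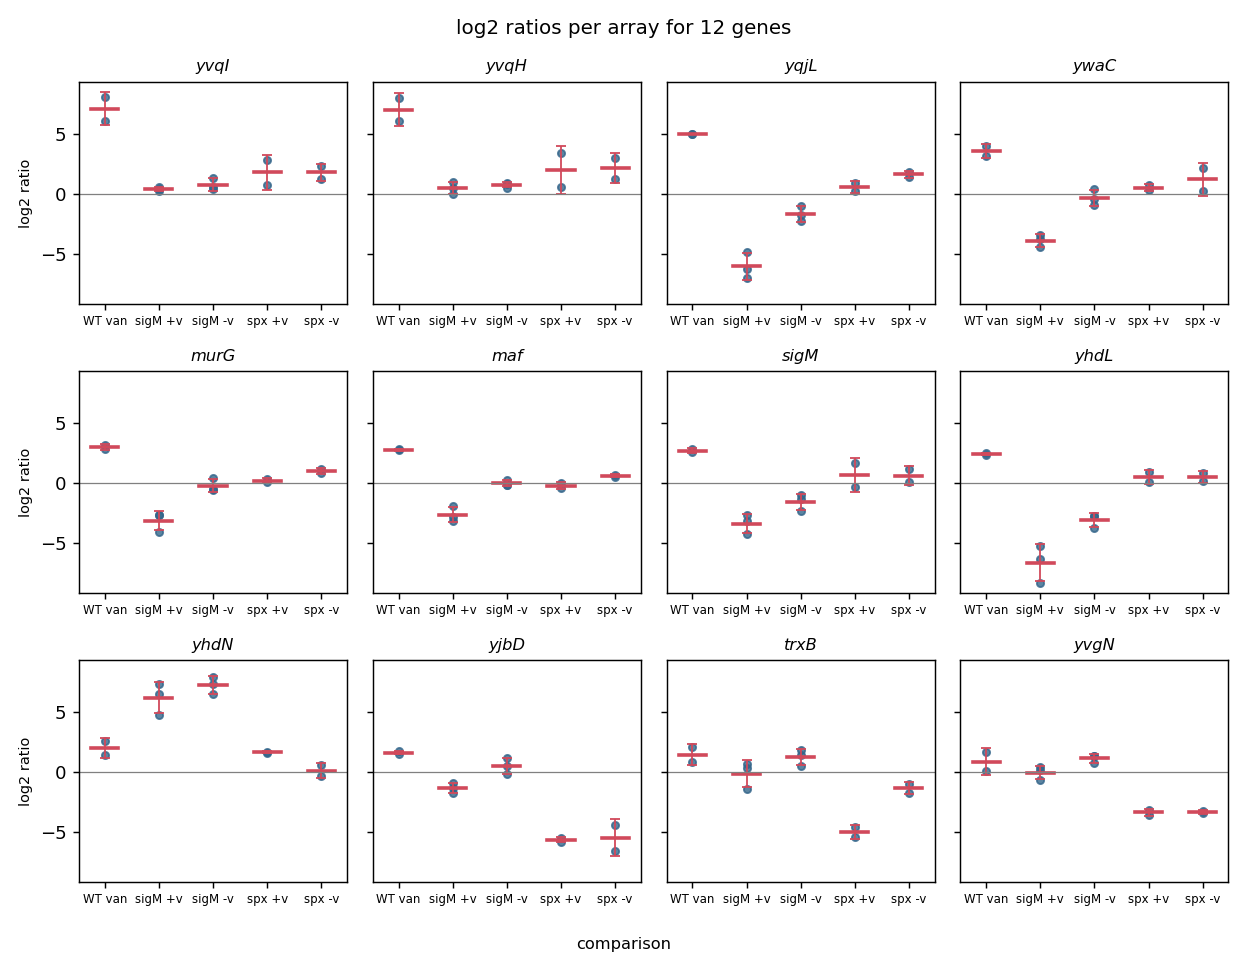
Log2 ratio on each array (vertical axis) for 12 genes in the 5 comparisons (horizontal axis: wild type with over without vancomycin, then mutant over wild type with (+v) and without (-v) vancomycin), where points are arrays, red bars the mean and whiskers the SD over 2 or 3 arrays. The genes yqjL and murG lay above 0 under vancomycin in wild type and below 0 in the sigM mutant with vancomycin, and yhdN lay near 7.30 in the untreated sigM mutant.

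The sigM mutant with vancomycin differed from wild type at 18 of 4053 genes, 2 higher and 16 lower. Beside sigM, yhdL and yhdK, the lowest were yqjL at -6.09 ± 1.09 (SD, n = 3), ypbG, a putative phosphoesterase gene, at -5.73 ± 2.32, ywaC at -3.91 ± 0.53, ydaH at -3.71 ± 1.35 and murB at -3.43 ± 0.65. Higher were yhdN, an aldo/keto reductase gene next to sigM in the reference gene order, at 6.23 ± 1.32 or 75.2-fold, and yxnA, an oxidoreductase gene, at 3.88 ± 1.21. The next highest, yqzD and yrhC, at 3.50 ± 1.12 and 3.48 ± 2.16, did not pass, and yqzD was dim.

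Of the sigM regulon list, 15 of 56 members were lower and 0 higher, 29 adjusted over the list alone, with a median at -1.48 relative to all genes, whose median was 0.33. Of the core targets, 8 of 16 were lower. In each list the lower members include sigM, yhdL and yhdK, the mutated gene and the genes transcribed with it. Both shifts held with an estimated correlation (adjusted p = 6.21e-05 and 0.000738 with an estimated correlation). Neither list is independent evidence, since these genes count in it and it was drawn in part from these arrays. In peptidoglycan synthesis, 3 of 34 members were lower: murB, murG at -3.17 ± 0.80 and the division gene divIB at -2.41 ± 0.25. The list test pointed down while the list median was 0.19 and its mean -0.25, and the call was lost with an estimated correlation (adjusted p = 0.717 with an estimated correlation). sbp, the single called lower gene outside every list, stood at -1.94 ± 0.22 and was named after its value was seen. The LiaRS list did not shift, with a median 0.05 above all genes and 0 of 6 members called (cameraPR adjusted p = 0.818), and the sigW list had a median 0.02 above all genes (0.707). The general stress list lay 0.54 above all genes with 1 of 30 members called, yhdN, while yvyD stood at 1.43 ± 0.47 and ytxH at 1.04 ± 0.31. The PBSX list lay at -0.57 and ribosomal proteins at -0.34 relative to all genes with 0 members called. On replicate 3 the PBSX median was -1.07, against 0.33 on each of the other arrays, and without replicate 3 both shifts were lost (medians of 0.29 for PBSX and 0.56 for general stress). The ribosomal shift was lost without replicate 1 (median -0.08) or replicate 2 (0.39), and with a dye term its median was 0.69 and the test pointed up. These 3 shifts were lost with an estimated correlation (adjusted p = 0.981 with an estimated correlation for each).

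Among the 18 genes raised by vancomycin in wild type, 8 were also lower in the sigM mutant with vancomycin: maf, murB, murG, radC, ycgR, ydaH, yqjL and ywaC. Independent lists of these sizes would share 0.0712 genes. Simulated groups that share wild-type RNA by replicate number gave an overlap of 0, but no gene was changed in them. An overlap near 0 was therefore set in advance, and it does not tell how much shared RNA adds to the overlap. Across genes the correlation of the log2 ratios was -0.145, against -0.412 in the simulation, and the covariance -0.09 against -0.167. The labels do not say whether arrays share wild-type RNA, and part of the excess overlap may come from it. The 5 called LiaRS genes were not called here, with yvqI at 0.41 and yvqH at 0.49. At an unadjusted p under 0.05 there were 422 genes. Leaving out replicate 2 called 8 genes, a separate limma fit of these arrays 0, a dye term 5 (1 higher and 4 lower) and array weights 36 (11 and 25). By at least 2-fold on every array without a test, 70 genes were higher and 35 lower.

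Without vancomycin, the sigM mutant differed from wild type at 12 of 4042 genes, 10 higher and 2 lower. The higher genes were led by yhdN at 7.30 ± 0.72 (SD, n = 3), or 158-fold, and yxnA at 5.58 ± 1.97. They were followed by blyA (an SPbeta lysin) at 4.21 ± 1.67, yuiH at 3.71 ± 1.72, ynaB at 3.48 ± 1.11 and yotC at 3.16 ± 0.63. Below them stood yvdC at 2.98 ± 1.16 and yxkO at 2.56 ± 0.24. Ratios of small whole numbers occurred for blyA and yotC on 5 of the 12 arrays each and for ynaB on 4. That falls short of the rule for dim, but their rises may be limits set by a dim wild-type channel. The lower genes were yhdK and yhdL. Next below, nin and yraI, at -2.16 ± 1.02 and -2.08 ± 0.43, did not pass and were dim. The whole array set leaned to the mutant channel: the median of all genes was 0.59, and the median of the 10 control probes was 0.95, with 9 of 10 above 0. After centring each array, 4 genes were called, 2 higher (50% of calls, against 83.3% as deposited) and 2 lower, and after scaling 6 higher and 1 lower.

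Of the sigM regulon list, 2 of 55 members were lower (yhdK and yhdL) and 0 higher, 3 and 1 adjusted over the list alone. These called members are transcribed with the mutated sigM. The list median was 0.03, which is -0.56 relative to all genes, so the sign of the median and the downward direction of the test differ. The shift held with an estimated correlation (adjusted p = 0.0286 with an estimated correlation), as did that of the core targets at -0.78 (adjusted p = 0.0305). With a dye term in the fit the regulon median was 0.12 and its shift was lost. yqjL stood at -1.69 ± 0.64 without passing. All 10 pyrimidine synthesis genes had means below 0, with a list median of -1.31 relative to all genes. 0 of them were called, pyrAB stood at -1.37 ± 2.26, and the adjusted p was 0.265 with an estimated correlation. Leaving out replicate 2 turned that list's median to 0.13. The general stress list lay 0.52 above all genes with 1 of 29 members called (yhdN), 9 adjusted over the list alone, among them yvyD at 2.19 ± 1.14. Its own median was 1.11, and 0.67 without replicate 1 or 1.67 without replicate 3. In the SPbeta list 2 of 41 members were higher (blyA and yotC) and the list did not shift (cameraPR adjusted p = 0.714). Ribosomal proteins lay at -0.51, peptidoglycan synthesis at -0.34, teichoic acids at -0.34 and PBSX at -0.49 relative to all genes, with 0 members called, while their own medians were above 0 (0.08, 0.25, 0.25 and 0.10). On replicate 3 the PBSX median was -0.57, against 0.53 and 0.58 on the other arrays, and without it the PBSX shift was lost (median 0.50), as was that of teichoic acids (0.54). Without replicate 2 the shifts of ribosomal proteins (0.53), peptidoglycan synthesis (0.22) and teichoic acids (0.26) were lost. With a dye term the tests of ribosomal proteins and PBSX pointed up (medians of 0.50 and 0.44). That term comes from the spx arrays with vancomycin alone, so it does not show a dye effect here. The adjusted p with an estimated correlation was 0.696 for the first 3 and for general stress, and 0.877 for PBSX. The comparisons with and without vancomycin shared yhdN and yxnA among the higher genes and yhdK and yhdL among the lower ones, against 0.00501 and 0.00802 genes for independent lists. The shared lower genes are transcribed with the mutated sigM, so their sharing comes with the strain. At an unadjusted p under 0.05 there were 846 genes. Leaving out replicate 1 or replicate 2 called 1 gene each, leaving out replicate 3 called 73, and a separate limma fit called 0. The planned limma fit of all 14 columns called 2 (2 higher), a dye term 1 (1 higher), a replicate block 5 (4 higher and 1 lower) and array weights 559 (551 and 8), and 170 genes were higher and 10 lower by at least 2-fold on every array.

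The interaction of genotype with vancomycin for sigM, from the strain arrays, called 0 of 3992 genes with limma, with 268 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0844. That gene was yqjL, whose mutant over wild-type ratio was lower by a difference of -4.40 ± 0.60 (SE) with vancomycin. The differences for ylxW, murB and ywaC were -3.30 ± 0.50, -3.13 ± 0.49 and -3.60 ± 0.61. As a set, the sigM regulon list had a median difference of -1.29, with 53 of 55 members below 0 and 24 lower adjusted over the list alone, and its core targets one of -2.16. Both held with an estimated correlation (adjusted p = 0.00236 and 0.0213). The lists hold sigM, yhdL and yhdK and were drawn in part from these arrays, so this is not independent evidence. The median of all genes was -0.27.

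The spx mutant with vancomycin differed from wild type at 190 of 4028 genes, 66 higher and 124 lower. The lowest were yvgP at -6.77 ± 2.60 (SD, n = 2), ywcH, a monooxygenase gene, at -5.89 ± 1.67, yjbD itself, yqiG, a flavin oxidoreductase gene, at -5.09 ± 0.99, and trxB, the thioredoxin reductase gene, at -5.04 ± 0.60 or 32.9-fold. yhaT stood at -4.76 ± 0.94, yyaE at -4.16 ± 0.56 and hxlR, an activator of formaldehyde detoxification, at -3.96 ± 0.16. The highest were xpf, a regulator of the defective prophage PBSX, at 5.55 ± 0.27, yhcC at 4.03 ± 1.91 and ykrT at 3.77 ± 1.35. Of these, xpf was dim, with small whole-number ratios on 6 arrays, and its limma SE was 1.12. The PBSX genes xkdM (3.46 ± 1.24), xkdN (3.38 ± 0.84), xhlA (3.33 ± 0.31), xhlB (3.32 ± 0.90) and xtmA (3.27 ± 0.80) followed. Without the dye-swapped array (replicate 2) 0 genes were called, and without replicate 1 there were 142.

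Of the PBSX list, 24 of 26 members were higher and 0 lower, 26 adjusted over the list alone, with a median of 2.94. Of the Spx-activated list, 4 of 13 were lower (trxB, ywcH, nfrA at -3.52 ± 0.48 and yojG, of bacillithiol synthesis, at -1.87 ± 0.62) and 0 higher, 7 adjusted over the list alone, with a median of -1.40. Of the general stress list, 6 of 29 were higher, 17 adjusted over the list alone, with a median of 1.90, among them gsiB at 2.87 ± 0.59, yxaB at 2.29 ± 0.10 and ytxJ at 2.09 ± 0.01. The sigW list had a median of 1.25 with 0 of 46 called, 4 adjusted over the list alone, and yuaG at 2.90 ± 1.24. Without the dye-swapped array its median was 0.29 and its shift was lost. These shifts passed at the preset correlation and not with an estimated one (adjusted p = 0.57 for PBSX, 0.899 for Spx-activated, 0.865 for general stress and 0.934 for sigW with an estimated correlation). Sulfate assimilation had a median of 1.56 and fatty acid synthesis one of 0.52. In the former the called member was the repressor gene yrzC (cymR) at -2.28 ± 0.49, and cysC stood at 2.15 ± 1.95, while fabHB stood at 1.79 ± 0.12. Both list shifts were lost with an estimated correlation (adjusted p = 0.966 and 0.934 with an estimated correlation) and after centring. Without the dye-swapped array the sulfate median was 0.67 and its shift was lost, and the fatty acid shift was lost without either array (0.47 and 0.66). Of the Spx-repressed list, 0 of 22 members were called (cameraPR adjusted p = 0.85). In the teichoic acid list tagG, of the wall teichoic acid exporter, and yqgS were lower, at -2.07 ± 1.17 and -1.62 ± 1.00. The sigM list had 1 of 56 members called, yjbD, and did not shift (cameraPR adjusted p = 0.85). Of the 190 genes, 151 lay in no list. At an unadjusted p under 0.05 there were 837 genes. Centring each array called 342 genes, scaling the arrays to a common spread called 3 (0 higher and 3 lower), and a separate limma fit called 0. The planned limma fit of all 14 columns called 64 (26 higher and 38 lower), a replicate block 296 (81 and 215), array weights 3 (0 and 3) and removal of dim probes 312 (120 and 192), and by at least 2-fold on both arrays 323 were higher and 359 lower.

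Without vancomycin, the spx mutant differed from wild type at 2 of 4064 genes, both lower: yjbD itself and yvgN, an aldo/keto reductase gene, at -3.35 ± 0.14 (SD, n = 2) or 10.2-fold. Next were yvgP at -4.16 ± 1.31 and yqiG at -4.01 ± 1.45, which did not pass. The highest, all PBSX genes, were xkdD at 4.34 ± 3.35, xkdN at 3.73 ± 2.35, the dim xpf at 3.54 ± 1.35 and xkdB at 3.42 ± 1.86, and none passed. The PBSX list had all 27 means above 0 and a median of 2.57, with 0 members called over all genes and 27 adjusted over the list alone (adjusted p = 5.74e-77 at the preset correlation and 0.15 with an estimated correlation). The Spx-activated list had a median of -0.90 with 0 of 14 called, nfrA at -1.69 ± 0.22 and trxB at -1.37 ± 0.50 (adjusted p = 0.74 with an estimated correlation), and with a dye term its median was -0.69 and its shift was lost. Motility and chemotaxis had a median of -0.35 with 33 of 35 means below 0 and 0 called, motB at -0.83 ± 0.48 (adjusted p = 0.828 with an estimated correlation), and without replicate 2 its median was -0.12 and its shift was lost.

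The spx comparisons with and without vancomycin shared yjbD and yvgN among lower genes, against 0.0622 for independent lists. Of these, yjbD is the mutated gene, so its sharing comes with the strain. The log2 ratios of these comparisons correlated across genes at 0.438. Simulated unchanged groups without shared RNA gave 0.008, a value near 0 that was set in advance. The spx interaction with vancomycin called 0 of 3989 genes with limma (smallest adjusted p = 0.804), with 238 at an unadjusted p under 0.05. A dye preference of a probe does not cancel in it, since only its arrays with vancomycin include a dye swap. The differences were -3.68 ± 0.81 (SE) for trxB, -3.95 ± 1.15 for ywcH and -0.14 for yjbD, so the larger count of called genes with vancomycin was not shown to differ gene by gene from that without. In the untreated comparison 242 genes had an unadjusted p under 0.05. Leaving out replicate 1 called 1 gene and leaving out replicate 2 called 0, scaling the arrays called 63 (41 higher and 22 lower), and a separate limma fit called 0. The planned limma fit of all 14 columns or a replicate block called 1 gene each, a dye term 0 and array weights 53 (37 higher and 16 lower), and by at least 2-fold on both arrays 146 were higher and 90 lower.

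**Figure D2:**
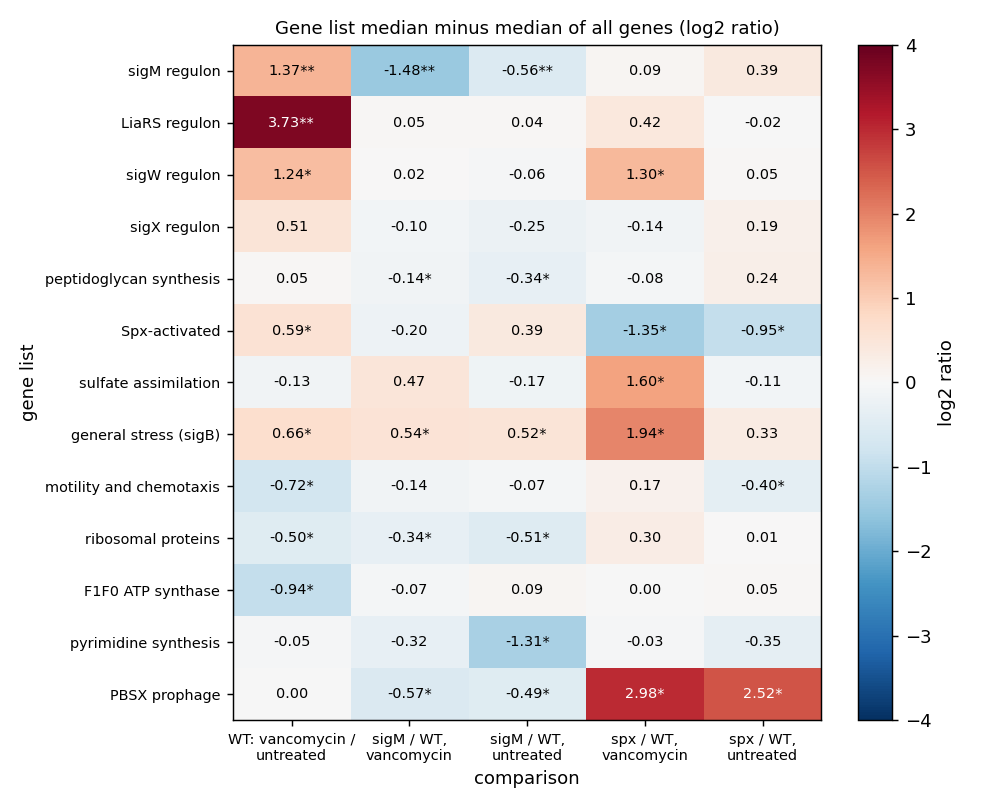
Median log2 ratio of 13 gene lists (vertical axis) minus the median of all genes in the 5 comparisons (horizontal axis), as a colour and a printed value, where entries with 1 asterisk passed the list test at the preset correlation alone and those with 2 asterisks passed with an estimated correlation as well. The latter are the sigM list in 3 comparisons (1.37, -1.48 and -0.56) and the LiaRS list under vancomycin in wild type (3.73).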

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

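The tests of the deposited columns, of dye preference, of dim probes, of the sigM locus and of the general stress list were chosen only after the results were seen, while the SOS list test, the flanking gene test and the counts over other splits were set before theirs.

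The difference between the mutant over wild-type ratios with and without vancomycin was tested for every list, and 11 lists passed at the preset correlation. For sigM, the regulon list had a median difference of -1.29 and its core targets one of -2.16, and both passed with an estimated correlation as well (adjusted p = 0.00236 and 0.0213). These lists hold the mutated sigM and were drawn in part from these arrays, so neither is independent evidence. The pyrimidine synthesis list had a median difference of 0.92 (adjusted p = 0.981 with an estimated correlation), and without untreated replicate 2 it was -0.15. For spx, a dye preference of a probe does not cancel in this difference, since only the arrays with vancomycin include a dye swap. The median differences were 1.18 for sigW, -0.47 for Spx-activated genes, 1.43 for sulfate assimilation and 1.43 for general stress. They were 0.45 for motility and chemotaxis, 0.25 for ribosomal proteins, 0.78 for fatty acid synthesis and 0.28 for PBSX. None of these 8 passed with an estimated correlation (adjusted p = 0.826, 0.922, 0.826, 0.736, 0.845, 0.922, 0.736 and 0.922 in that order). After the arrays were scaled to a common spread the PBSX difference lay the other way, at -1.22 relative to all genes, and without untreated replicate 1 its median was -0.24. The ribosomal protein difference lay the other way, at -0.21, without the dye-swapped array. With a dye term it was -0.21, and the median differences of sigW and sulfate assimilation were 0.36 and 0.57. These equal the values without the dye-swapped array, since the dye term is estimated only from the spx pair with vancomycin. They are therefore no second check.

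The sigM interaction called 0 genes with limma, with 268 at an unadjusted p under 0.05. With a count of 0, all 10 of the 10 splits of these 6 arrays must give at least as many (the highest of the others was 0), so this count over splits says nothing. The sigM comparison with vancomycin called 18 genes on the real signs, and 1 of the 4 sign patterns of its 3 arrays gave as many, the highest of the others being 1. Without vancomycin the real count was 12, reached by 1 of 4 patterns, with 0 as the highest of the others. With 4 patterns a share under 0.05 cannot be reached.

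The columns deposited for the response of the sigM mutant to vancomycin equalled differences of other columns in 100% of 4110 rows, against at most 5.31% for other triples of columns. They were missing in all 6 rows where a wild-type vancomycin array had no value. By the test of arithmetic of the deposited table, these values are consistent with columns computed from the wild-type arrays in place of measured ratios. No biological explanation was tested, since no measured ratio of these arrays was used here.

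The PBSX genes stood higher in the spx mutant in both conditions, with all measured members of the list above 0 on every spx array, but with an estimated correlation the list passed in neither (adjusted p = 0.57 with vancomycin and 0.15 without), and without vancomycin 0 of 27 members were called. A dye preference of the probes would turn the sign on the dye-swapped array, where the median was 3.04, and 1 of 27 members was dim, which argues against values near background. A chromosomal segment wider than the prophage is argued against by the flanking genes, whose median was -0.20 with vancomycin (12 genes) and -0.19 without (13 genes), although xlyB among them stood at 2.99 and 2.83, and xre, inside the prophage but not in the list, at -1.79 and 0.10. An SOS response as a whole may contribute and cannot be told apart. The SOS list lay 0.505 above all genes with vancomycin and 0.144 without and did not pass cameraPR in either condition. With vancomycin 9 of its 12 members stood above 0, among them yneA (2.93, but dim), tagC (1.48) and dinB (1.24). Lower values were those of recA (-0.06), lexA (0.23), uvrA (-0.87), uvrB (-0.43), ruvA (0.32) and ruvB (0.07). The loss of spx itself, or a difference between the strains in the prophage, stays open as untested.

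The genes yhdN and yxnA stood higher in the sigM mutant in both conditions. A dye preference is argued against by the untreated spx arrays of the same dye orientation, where they stood at 0.11 and 0.62, a difference of at least 4.96 from the sigM arrays. For yxnA, a disrupted neighbourhood of sigM is argued against by the 1214 genes between them, while yhdN lies next to sigM, and transcription reading out of the disrupted locus may account for it. That cannot be told apart here, since of the genes named in series after yhdN the untreated means were 2.15 for yhdO, which was dim on 10 arrays, and 0.13 for yhdP. A rise of general stress genes as a set is argued against as the whole cause, since both genes lay further above that list (without yhdN) on the sigM arrays than on the spx arrays with vancomycin, by at least 2.47 ± 1.03 (SE, yxnA with vancomycin), while the loss of sigM as such was not tested apart from the locus.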

How the results depend on the processing

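The fit of all 14 columns was the plan made before the data were seen, and leaving out 2 columns was decided after. By their arithmetic those columns widen the spread of genes that respond to vancomycin in wild type, so that fit is no independent check. Removing dim probes and the general stress list without yhdN were chosen after seeing the data, and the other alternatives were set before. Counts of called genes are given as deposited first. For vancomycin in wild type (18) they were 0 in a separate fit of its arrays, 4 with a replicate block, 4 with a dye term, 44 with array weights, 0 in the planned fit of all 14 columns and 283 (192 higher, 91 lower) when only a 2-fold change on every array was asked for, and 3 to 27 when 1 array was left out. For sigM with vancomycin (18) they were 0 in a separate fit, 5 with a dye term (1 higher, 4 lower), 36 with array weights, 105 by the 2-fold rule (70 higher, 35 lower) and 8 to 18 with 1 array left out. For sigM untreated (12) they were 4 when centred, 7 when scaled, 0 in a separate fit, 5 with a replicate block, 1 with a dye term, 559 with array weights (551 higher, 8 lower), 2 with all 14 columns, 180 by the 2-fold rule (170 higher, 10 lower) and 1 to 73 with 1 array left out. For spx with vancomycin (190) they were 342 when centred, 3 when scaled, 0 in a separate fit, 296 with a replicate block, 3 with array weights, 64 with all 14 columns, 312 with dim probes removed, 682 by the 2-fold rule and 0 to 142 with 1 array left out. For spx untreated (2) they were 63 when scaled, 0 in a separate fit, 1 with a replicate block, 0 with a dye term, 53 with array weights, 1 with all 14 columns, 236 by the 2-fold rule and 0 to 1 with 1 array left out. The sigM interaction (0 with limma, 268 at an unadjusted p under 0.05) had 21 with array weights, 3 with dim probes removed and 0 to 4 with 1 array left out. The spx interaction (0 with limma, 238 at an unadjusted p under 0.05) stayed at 0 with each array left out. A separate fit has fewer residual degrees of freedom, and where 1 array was left of a pair it was assumed to vary like the other groups. The dye term rests on the spx pair with vancomycin alone, so counts with it are no test of the dyes of other comparisons. For the other changes, those of lists included, the cause was not tested.

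All 45 list shifts past the threshold were recomputed, and medians follow for those that were lost or turned. The dye term carries a difference between the dye-swapped array and its partner into the other comparisons. In the spx interaction it repeats the result without the dye-swapped array. With a dye term, shifts were lost for the sigM regulon (0.12), pyrimidine synthesis (-0.087), peptidoglycan synthesis (0.16) and teichoic acids (0.22) in sigM untreated, PBSX in sigM with vancomycin (-0.054), SPbeta in wild type (0), fatty acid synthesis in spx with vancomycin (0.52), Spx-activated genes in spx untreated (-0.69), and sigW (0.36), sulfate (0.57) and PBSX (0.080) in the spx interaction. With it the tests of ribosomal proteins turned in wild type (0.064), sigM with vancomycin (0.69), sigM untreated (0.50) and the spx interaction (-0.21), as did that of PBSX in sigM untreated (0.44). With a replicate block the ribosomal test turned in wild type (0.018), and shifts were lost for purine synthesis in wild type (-0.28), motility in spx untreated (-0.26) and ribosomal proteins in the spx interaction (-0.0035). When centred, shifts were lost for ribosomal proteins in sigM with vancomycin (-0.33) and the spx interaction (0.32), and for sulfate (1.63) and fatty acid synthesis (0.60) in spx with vancomycin. When scaled, those lost were sulfate (1.00) and fatty acid synthesis (0.38) in spx with vancomycin and Spx-activated genes (-0.053) and ribosomal proteins (0.12) in the spx interaction, where PBSX turned (-1.31). Array weights ended the shifts of PBSX in sigM with (0.11) and without vancomycin (0.28), teichoic acids in sigM untreated (0.32), and sulfate (1.56) and fatty acid synthesis (0.52) in spx with vancomycin. Separate fits ended those of SPbeta in wild type (0.59), ribosomal proteins in sigM with vancomycin (-0.0018), peptidoglycan synthesis in sigM untreated (0.25), sulfate (1.56) and fatty acid synthesis (0.52) in spx with vancomycin, and sulfate (1.43), ribosomal proteins (0.248) and PBSX (0.28) in the spx interaction. All 14 columns ended those of SPbeta in wild type (0.59), teichoic acids in sigM untreated (0.25), fatty acid synthesis in spx with vancomycin (0.52) and Spx-activated genes in the spx interaction (-0.47). Sulfate in spx with vancomycin was lost with dim probes removed (1.575) and over complete genes (1.575), fatty acid synthesis there over complete genes (0.52), and SPbeta in wild type with dim probes removed (0.50).

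With 1 array left out, medians of lists that then lost or turned a shift ran as follows. In wild type they ran from 0.39 to 1.04 for Spx-activated genes, 0.37 to 1.26 for general stress, -0.45 to -0.30 for ribosomal proteins, -1.15 to -0.30 for purine synthesis, -0.049 to 1.42 for SPbeta (turned without replicate 2) and -1.44 to -0.23 for the ATP synthase. In sigM with vancomycin they ran from 0.56 to 1.12 for general stress, -0.27 to 0.39 for ribosomal proteins and -0.51 to 0.29 for PBSX. In sigM untreated they ran from -1.75 to 0.13 for pyrimidine synthesis, 0.16 to 0.29 for peptidoglycan synthesis, 0.020 to 0.54 for teichoic acids, -0.42 to 0.53 for ribosomal proteins and 0.011 to 0.50 for PBSX. In spx with vancomycin they ran from 0.29 to 2.03 for sigW, 0.67 to 2.42 for sulfate and 0.47 to 0.66 for fatty acid synthesis, and in spx untreated from -0.57 to -0.12 for motility. In the sigM interaction they ran from -0.15 to 1.72 for pyrimidine synthesis. In the spx interaction they ran from 0.36 to 1.93 for sigW, -0.75 to -0.11 for Spx-activated genes, 0.57 to 2.29 for sulfate and -0.11 to 1.07 for motility. There ribosomal proteins ran from -0.21 to 0.86 and PBSX from -0.24 to 0.89, turned without the dye-swapped array and without untreated replicate 1 respectively. Without yhdN the general stress median was 0.84 and 1.09 in the sigM mutant with and without vancomycin. Of 45 list shifts past the threshold, 41 stayed past it when centred and 41 when scaled, and 1 lay the other way when scaled. Of 571 alternative values of called named genes, 371 stayed called, 200 kept their direction without being called and 0 lay the other way.

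Whether the replicate numbers pair the arrays could not be told. Of 13 pairs of the same number, 1 correlated above 0.1 and 3 below -0.1, with a range from -0.127 to 0.208. Shared wild-type RNA would give either sign, depending on the comparisons. The deviations in a group of 2 arrays mirror each other, so the pairs are not independent. A fit of the arrays as a network was not run, since without the 2 unused columns it equals the fit by groups. Separate tests of several probes of a gene were not run, since each gene has 1 row. Intensities were not used here, so how far dim signals limit each ratio is unknown.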

Other observations

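The whole-number ratio values and control probe values were chosen only after the data were seen. Of the 190 genes called in the spx mutant with vancomycin, 151 lay in no list, 36 higher and 115 lower. In the SPbeta prophage list 34 of 41 genes were dim, 82.9% against 23.4% of other genes. The median of the 10 control probes was 0.11 for vancomycin in wild type, 0.31 and 0.95 for sigM with and without vancomycin, and -0.26 and 0.22 for spx with and without it, while the median of all genes was 0.10, 0.33, 0.59, -0.04 and 0.05.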
